A study of Homo sapiens with 6 samples.

How the data were processed

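The data are 6 arrays of total RNA from HuH7 cells, 3 from cells given a control gapmer and 3 from cells given a gapmer against EGOT. Per the labels' protocols, each well was seeded with 100000 cells and received 50 pmol of gapmer, 0.3 µg of the PKR plasmid among other plasmid DNA, and poly I:C. RNA was taken 36 hours after transfection, its quality was examined on a Bioanalyzer, and 6 µg entered labelling for an Affymetrix whole-transcript array of the Human Gene ST kind. The labels do not say whether replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The design holds 1 gapmer against EGOT and 1 control gapmer, and no samples without PKR and poly I:C.

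The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes quantiles between arrays and summarises probes into probe sets on the log2 scale. Its version, the software and any filter on probe sets are not given in the sources used here. That the scale is log2 follows from RMA and from the values, which run from 1.05 to 14.1 and are not centred per probe set. Array medians still differ, from 5.08 to 5.23, so the table is not exactly quantile-normalized over its own probe sets. Because RMA sets the arrays to a shared distribution, a change in the total amount of RNA per cell would not be seen. Values near the low end carry mostly background, which compresses differences there.

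Probe sets were named from GEO's platform annotation. Of 44629 probe sets, 15835 (35.5%) had 1 gene symbol, 0 had several and 28794 were not named here and stayed out of the gene tests. All symbols matched the NCBI RefSeq gene table of assembly GRCh38.p14, and 0 needed updating. The named genes included 11911 protein-coding genes, 1387 long noncoding RNAs and 1022 microRNA genes. A gene with several probe sets (651 genes) was represented by the one with the highest mean over the 6 arrays. In 67 of these genes only some probe sets passed the threshold, and in 0 did probe sets pass in opposite directions. The 6 values were identical to those of another probe set in 1475 probe sets, which affected 77 named genes.

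Groups were compared as EGOT gapmer minus control gapmer with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, a two-sided test and Benjamini-Hochberg adjustment over 14812 genes, with a threshold of 0.05 on the adjusted p. The variance shared across genes raised the degrees of freedom to 7.19. EGOT was also tested with a two-sided exact permutation test over the 20 assignments of the 6 arrays. Gene lists, 23 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 21 lists with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry tests it against no change. A shift shared by many genes can therefore make a list pass by fry. Of the other 2 lists, the fibroblast and stellate cell list had 4 measured members and is given as values, and the replication-dependent histone list had 0. Tested lists were measured only in part, such as 35 of 50 interferon-stimulated, 12 of 36 oxidative phosphorylation and 6 of 21 MHC class I genes. With an estimated correlation 0 of the 21 lists passed, against 9 with the preset one, and the smallest adjusted p was 0.112.

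The comparison, the lists, the rule for naming genes and the alternatives were set before the data were examined, except where the text says otherwise. Named genes are EGOT, ITPR1 and EIF2AK2; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out uncharacterised loci, small RNAs, antisense transcripts and similar symbols and numbered pseudogenes; the 4 members of each list with the smallest p; and 9 preset antiviral genes. The filter on pseudogenes was narrowed after the data were seen to symbols annotated as pseudogenes, since it had also removed genes such as AQP3. TAAR3P stayed because its symbol has no digits at its end. Where 5 or fewer members of a list passed, or the text gives all that passed, further members such as DDIT3, SHMT2 and CCNB1 were named after their values were seen. Of the named genes 6, ITPR1, GBP1, MX1, IFI6, IFNB1 and IFNL1, were not analysed here. Gene spans are genomic lengths from the RefSeq table and serve only to compare genes, and the brighter protein-coding genes are those above the median of the gene means.

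The fit was tested on data simulated from these 14812 genes with 200 changed. It recovered 43% of 100 genes changed by 0.5 on the log2 scale and 87% of 100 changed by 1, with 6 false calls among 136. Of 50 unchanged simulated lists of 30 genes 0 were called by limma's camera, and a list shifted by 0.3 was called higher. The simulated noise was independent between genes, so this does not test the preset correlation for lists whose members vary together. The estimated correlation of the interferon-stimulated gene list was 0.512. The alternatives were another quantile normalization, cyclic loess, median centring, the brighter genes alone, a variance trend with robust estimation, array weights, the replicate number as a block, 2 other treatments of several probe sets, a test against a log2 difference of 0.26, and leaving out each array. Removal of each array's lowess trend on gene span was added after the data were seen. No scan date or other batch is given in the sources used here, so a batch that followed the groups cannot be told apart from the gapmer.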

Results

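EGOT is a long noncoding RNA transcribed from within an intron of ITPR1 on the short arm of chromosome 3. It was named after eosinophil granule development and is known to be induced by viral infection and by double-stranded RNA. Gene expression was measured in HuH7 cells, a human hepatoma line, after transfection with a gapmer against EGOT or with a control gapmer. A gapmer is a short oligonucleotide with modified ends and a DNA centre that directs RNase H to cleave a complementary RNA. The sequence given for EGOT was AGAGACACTTAGAAGA, and that given for the control was AACACGTCTATACGC. All 6 samples also received a plasmid expressing PKR, the kinase activated by double-stranded RNA, and poly I:C, a synthetic double-stranded RNA, with the stated purpose of inducing EGOT. RNA was taken 36 hours later. There were 3 control gapmer arrays and 3 EGOT gapmer arrays, and the comparison asks which transcripts differ when EGOT is depleted under these conditions.

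Each array gave a log2 expression value for 44629 probe sets, of which 15835 carried a gene symbol and stood for 14812 genes. The median over all probe sets was 5.15, 5.12 and 5.12 in control gapmer replicates 1 to 3. It was 5.12, 5.23 and 5.08 in EGOT gapmer replicates 1 to 3. Correlations across all probe sets were 0.991 to 0.992 within the control gapmer arrays, 0.987 to 0.989 within the EGOT gapmer arrays and 0.985 to 0.988 between the groups. The first principal component held 41.7% of the variance and separated the groups, with scores of -14.1 to -13.3 for the control gapmer and 8.76 to 19.4 for the EGOT gapmer. EGOT gapmer replicate 2 lay apart from the rest on the second component, with a score of 16.9, and had the highest median. The precision of every value is limited by the 3 arrays per group.

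EGOT fell in the EGOT gapmer arrays. Its log2 level was 6.59 ± 0.269 (SD, n = 3) with the control gapmer and 4.83 ± 0.126 (SD, n = 3) with the EGOT gapmer. The log2 difference was -1.76 with a standard error of 0.142, which is 0.295 of the control level (limma adjusted p = 0.0076). The control gapmer arrays read 6.29, 6.79 and 6.71, and the EGOT gapmer arrays read 4.91, 4.90 and 4.69, so the groups did not overlap. A two-sided exact permutation test of these 6 values gave p = 0.1, the smallest value that 3 arrays against 3 allow. The part of EGOT read by its probe set was not located relative to the gapmer site. ITPR1, the host gene, was not analysed here. EIF2AK2, the gene for PKR, also fell, from 11.25 ± 0.0224 to 10.68 ± 0.0806 (SD, n = 3 each, limma adjusted p = 0.0119). Its log2 difference was -0.57 with a standard error of 0.0720. Whether its probe set reads the plasmid transcript, the cell's own transcript or both was not given in the sources used here.

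Beyond EGOT, the genes that fell most included 4 genes known to be induced by interferon. IFI44L fell by 1.48 on the log2 scale, RSAD2, which encodes the antiviral enzyme viperin, by 1.36, DDX60L by 1.36 and DDX60, a helicase that promotes sensing of viral RNA, by 1.01. The other leading falls were in genes of varied function. TBL1XR1, part of a nuclear corepressor complex, fell by 1.37, the ephrin receptor gene EPHA5 by 1.19, and TAAR3P, a transcribed pseudogene of a trace amine receptor, by 1.18. The cell-surface proteoglycan gene GPC6 and COG6, part of a Golgi tethering complex, each fell by 1.11. The zinc finger gene HIVEP2 fell by 1.06 and FRYL by 1.05, though the mean of HIVEP2's probe sets had a smaller log2 difference of -0.42. Limma adjusted p-values of these genes lay between 0.00476 for TBL1XR1 and HIVEP2 and 0.0142 for EPHA5.

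Among the genes that rose, TSPYL2, a nucleosome assembly family member, was 2.10-fold higher, with a log2 difference of 1.07 and a standard error of 0.0720 (limma adjusted p = 0.00476). CD68, a lysosomal glycoprotein gene used as a macrophage marker, rose by 1.06 on the log2 scale and MTMR11, of the myotubularin family, by 1.05. AQP3, a water and glycerol channel gene, rose by 1.04 and ACSL5, which activates long-chain fatty acids, by 1.03. The aminoacylase gene ACY3 rose by 0.98, GPX2, a glutathione peroxidase gene, by 0.91 and the synaptic vesicle gene SV2A by 0.91. MT1H, a metallothionein gene, rose by 0.90, NTAN1, an amidase of the N-end rule pathway, by 0.87, CYB5D1 by 0.87 and the apolipoprotein gene APOA4 by 0.85. APOA4 had the highest limma adjusted p of these, 0.0364. MT1H and APOA4 no longer passed once the trend on gene span, described below, was removed. They were then at 0.83 (limma adjusted p = 0.0548) and 0.77 (limma adjusted p = 0.0578). With 1 array left out they passed only without EGOT gapmer replicate 1. GPX2 did not pass when EGOT gapmer replicate 1, 2 or 3 was left out.

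In all, 1245 of the 14812 genes passed the threshold, 770 higher and 475 lower with the EGOT gapmer (limma, Benjamini-Hochberg). A rise of at least 1.5-fold was seen in 119 of them and a fall of at least that size in 92. A rise of at least 2-fold was seen in 7 and such a fall in 15. At an unadjusted p under 0.05 there were 3708 genes, 2406 higher and 1302 lower. The 3 values of one group all lay on one side of the other group's in 4699 genes, or 31.7%, where chance gives 10%. The balance of directions depended on the scaling, with 61.8% of calls higher in the values as deposited, 50.2% after another quantile normalization (679 higher, 674 lower) and 48.8% after cyclic loess (644 higher, 677 lower). The number of calls fell to between 9 and 579 when 1 array was left out, being 58, 9 and 34 without control gapmer replicates 1, 2 and 3 and 579, 505 and 156 without EGOT gapmer replicates 1, 2 and 3.

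**Figure D1:**
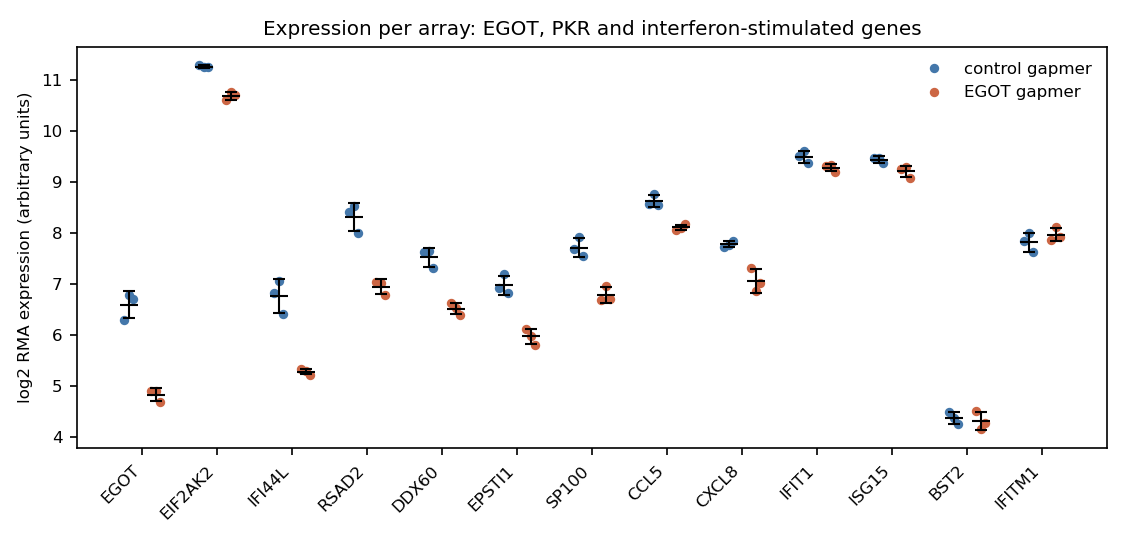
Log2 RMA expression of EGOT, EIF2AK2 (PKR) and antiviral and chemokine genes, with 1 point per array for the control gapmer (blue) and the EGOT gapmer (orange), bars giving the mean and SD of 3 arrays. The EGOT points lie between 6.29 and 6.79 for the control gapmer and between 4.69 and 4.91 for the EGOT gapmer, whereas the BST2, IFIT1, IFITM1 and ISG15 differences did not pass the test.

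Interferon-stimulated genes were lower as a group. Of 35 measured members, 32 had a log2 difference below 0, 15 fell and 0 rose, and 24 fell when adjusted over the list alone. The list's median log2 difference was -0.39. Besides IFI44L and RSAD2, EPSTI1 fell by 1.00 and SP100, a nuclear body protein gene, by 0.93. The mean over the list was 7.45, 7.57 and 7.31 in the control gapmer arrays and 7.02, 7.13 and 6.94 in the EGOT gapmer arrays. The camera test of the list gave an adjusted p of 8.44e-15, and an adjusted p = 0.278 with an estimated correlation. Several well-known members did not pass. ISG15, a ubiquitin-like modifier, had a log2 difference of -0.23 (limma adjusted p = 0.140) and IFIT1 of -0.22 (limma adjusted p = 0.176). BST2, or tetherin, had one of -0.05 (limma adjusted p = 0.816) and IFITM1 of 0.14 (limma adjusted p = 0.516). The log2 level of BST2 was 4.37 with the control gapmer and 4.32 with the EGOT gapmer, below the median of every array. A change in BST2 could therefore be missed. In the alternatives ISG15 passed in 2 of 10, IFIT1 in 1 of 10, and BST2 and IFITM1 in 0. GBP1, MX1, IFI6, IFNB1 and IFNL1 were not analysed here.

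Cytokine and antigen presentation genes were also lower as lists. Of 17 measured interferon, cytokine and chemokine genes, 3 fell and 0 rose, with 6 falling when adjusted over the list alone. CSF1, a macrophage growth factor gene, fell by 0.66 on the log2 scale, and the chemokine genes CXCL8 and CCL5 fell by 0.72 and 0.51. CXCL9 had a log2 difference of -0.62 that did not pass (limma adjusted p = 0.0505), though it did, at -0.71, once the trend on gene span was removed (limma adjusted p = 0.0450). The list's median was -0.29 (camera adjusted p = 2.33e-06), with an adjusted p = 0.112 with an estimated correlation. Of 21 genes in the list of MHC class I antigen presentation only 6 were measured, so most of the list was not assessed. All 6 were below 0, and 1 fell, TAPBP, which encodes the peptide-loading protein tapasin, by 0.38. When adjusted over the list alone 2 fell. The median was -0.19 (camera adjusted p = 0.0165, adjusted p = 0.262 with an estimated correlation). ERAP1, a peptide-trimming enzyme, had a difference of -0.32 that did not pass (limma adjusted p = 0.0765).

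Genes that sense viral RNA and NF-kB target genes were lower by smaller medians. Of 16 measured sensing and signalling genes, 3 fell and 0 rose, and 4 fell when adjusted over the list alone. The genes that fell were EIF2AK2, TRIM25, a ubiquitin ligase acting on RIG-I, by 0.54 on the log2 scale, and IFIH1, which encodes the sensor MDA5, by 0.45. RIGI itself had a difference of -0.50 that did not pass (limma adjusted p = 0.0613), though it passed in 5 of 10 alternatives. The median was -0.10 (camera adjusted p = 0.00953, adjusted p = 0.278 with an estimated correlation). Of 18 measured NF-kB target genes, 3 fell and 1 rose. NFKB1 fell by 0.50, the adhesion molecule gene ICAM1 by 0.43 and IRF1 by 0.45, whereas ZC3H12A, which encodes an RNase that degrades cytokine transcripts, rose by 0.41. Adjusted over the list alone, 4 fell and 1 rose. ZC3H12A had a difference of 0.32 and no longer passed once the trend on gene span was removed (limma adjusted p = 0.0677). The median was -0.09 (camera adjusted p = 0.0216, adjusted p = 0.49 with an estimated correlation). Without EGOT gapmer replicate 1 the camera adjusted p of the NF-kB list was 0.0811.

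Heat shock genes were higher as a group, and single genes of the ATF4 response rose. All 9 measured genes of the heat shock list, which includes HSPD1 of the mitochondrial chaperonin, had a log2 difference above 0, with 3 rising and 0 falling, and 6 rising when adjusted over the list alone. The small heat shock protein gene HSPB1 rose by 0.52, HSPA1B, which encodes an HSP70, by 0.34 and its co-chaperone gene BAG3 by 0.32. The median was 0.29 (camera adjusted p = 0.00276, adjusted p = 0.238 with an estimated correlation). With the trend on gene span removed the list still passed (median 0.21, camera adjusted p = 0.00585), while HSPA1B, at 0.26 (limma adjusted p = 0.0672), and BAG3, at 0.25 (limma adjusted p = 0.0977), no longer did. In the list of genes of the eIF2alpha-ATF4 stress response, which PKR can activate, 6 of 17 measured members rose and 0 fell. They were DDIT4, by 0.65, DDIT3, by 0.66, ASNS, by 0.40, ATF4, by 0.41, PHGDH, by 0.32, and SHMT2, by 0.29, and adjusted over the list alone 7 rose and 1 fell. The median of 0.12 did not pass (camera adjusted p = 0.115), but it did without EGOT gapmer replicate 2 (camera adjusted p = 0.0413). With the trend on gene span removed 2 members rose and the median was 0.07 (camera adjusted p = 0.276). Of 9 endoplasmic reticulum chaperone genes 0 passed, over all genes or adjusted over the list alone. Their median was 0.02, whereas their mean was -0.02 and the camera test pointed down (camera adjusted p = 0.459). XBP1 had a difference of -0.21 (limma adjusted p = 0.134) and passed in 3 of 10 alternatives, among them the removal of the trend on gene span (-0.30, limma adjusted p = 0.0468).

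Ribosomal protein genes were higher as a group. Of 31 measured, 9 rose and 0 fell, and 19 rose when adjusted over the list alone. RPL28 rose by 0.49, RPS7 by 0.38, RPL35 by 0.37 and RPL30 by 0.36. The median was 0.23 (camera adjusted p = 3.48e-08, adjusted p = 0.262 with an estimated correlation). With the trend on gene span removed 0 members passed singly, and the list still did, with a median of 0.13 (camera adjusted p = 4.68e-06). Among 12 nuclear genes of oxidative phosphorylation, all with differences above 0, COX6B1 rose by 0.34, and adjusted over the list alone 3 rose. COX6B1 passed in 7 of 10 alternatives, but not with the trend on gene span removed (0.24, limma adjusted p = 0.0936). The median was 0.19 (camera adjusted p = 0.00953, adjusted p = 0.278 with an estimated correlation). Of 16 cholesterol biosynthesis genes 2 rose, IDI1 by 0.49 and MVD by 0.39, with 4 rising when adjusted over the list alone. MVD no longer passed with the trend on gene span removed (0.30, limma adjusted p = 0.0616). The median was 0.17 (camera adjusted p = 0.0165, adjusted p = 0.49 with an estimated correlation), and without EGOT gapmer replicate 3 the camera adjusted p was 0.0844. Of 14 hypoxia and glycolysis genes 2 rose, PGM1 by 0.46 and the mitophagy receptor gene BNIP3L by 0.44, and 6 rose when adjusted over the list alone. BNIP3L no longer passed with that trend removed (0.37, limma adjusted p = 0.0602). Their median of 0.21 did not pass (camera adjusted p = 0.0594), though it did without EGOT gapmer replicate 1 (0.0395) or replicate 2 (0.0413).

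Some liver and proliferation genes passed the test singly, while their lists did not pass except in alternatives given below. Of 27 hepatocyte secreted protein genes 3 rose, by either adjustment. They were HPX, the haem carrier hemopexin, by 0.39, KNG1, kininogen, by 0.36, and APOA1, the main apolipoprotein of HDL, by 0.36. The median was 0.06 (camera adjusted p = 0.143, 0.0413 without EGOT gapmer replicate 2, and by fry an adjusted p of 0.0214). With the trend on gene span removed HPX still passed, at 0.29, and KNG1, at 0.28 (limma adjusted p = 0.0728), and APOA1, at 0.29 (limma adjusted p = 0.102), did not. Of 16 acute phase genes HAMP, which encodes the iron hormone hepcidin, fell by 0.53 and was the 1 that passed by either adjustment (median 0.06, camera adjusted p = 0.684). Of 32 cell cycle genes 4 rose and 1 fell. BIRC5, which encodes survivin, rose by 0.51, the replication licensing genes CDT1 and MCM2 by 0.39 and 0.30 and CCNB1 by 0.34, whereas MKI67 fell by 0.47. Adjusted over the list alone 6 rose and 3 fell (median 0.08, camera adjusted p = 0.103, 0.0423 with a variance trend, and by fry an adjusted p of 0.0488). MCM2 passed in 5 of 10 alternatives, and with the trend on gene span removed 1 gene of the list rose and 3 fell. Of 11 p53 target genes CCNG1 rose by 0.39, and 2 rose when adjusted over the list alone (median 0.09, camera adjusted p = 0.402, and by fry an adjusted p of 0.0305). CCNG1 no longer passed with that trend removed (0.31, limma adjusted p = 0.0614).

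None of the lists of markers of other cell types passed by camera with 1 probe set per gene. Of 8 measured leukocyte marker genes 2 rose, by either adjustment, CD68 and LYZ, the lysozyme gene, the latter by 0.57, or by 1.13 as the mean of its probe sets (list median 0.25, camera adjusted p = 0.143). The leukocyte list passed with every probe set tested (camera adjusted p = 0.0288) and by fry (adjusted p = 0.0305). The T cell marker gene CD2 had a difference of 0.34 (limma adjusted p = 0.229). Of 9 endothelial genes 0 passed by either adjustment. Their median was -0.05 and their mean 0.0034 (camera adjusted p = 0.684, downward). Of 6 eosinophil genes 0 passed by either adjustment, with a median of 0.06, whereas the camera test pointed down (adjusted p = 0.684). Of 4 measured fibroblast and stellate cell genes, too few for a list test, 0 passed and the median was -0.08. Some genes of these lists were dim with the control gapmer, such as SIGLEC8 at 3.35, KDR at 3.76 and DCN at 2.37, below the median of every array. Others, such as GATA1 at 6.46, were brighter. Changes in the dim genes could be missed. Of 8 epithelial-mesenchymal transition genes SNAI1, a transcriptional repressor, rose by 0.80 and ZEB2 fell by 0.32, by either adjustment. ZEB2 lay at the threshold (limma adjusted p = 0.0486) and passed in 1 of 9 alternatives (0.0494 to 0.115). Their median was 0.01, with the camera test pointing down (adjusted p = 0.991). Of 5 measured genes near EGOT on chromosome 3 SUMF1 fell by 0.49 (limma adjusted p = 0.0380), by either adjustment, and the list's median was -0.01 (camera adjusted p = 0.649). SUMF1 passed in 8 of 10 alternatives, but not with the trend on gene span removed (-0.33, limma adjusted p = 0.130).

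**Figure D2:**
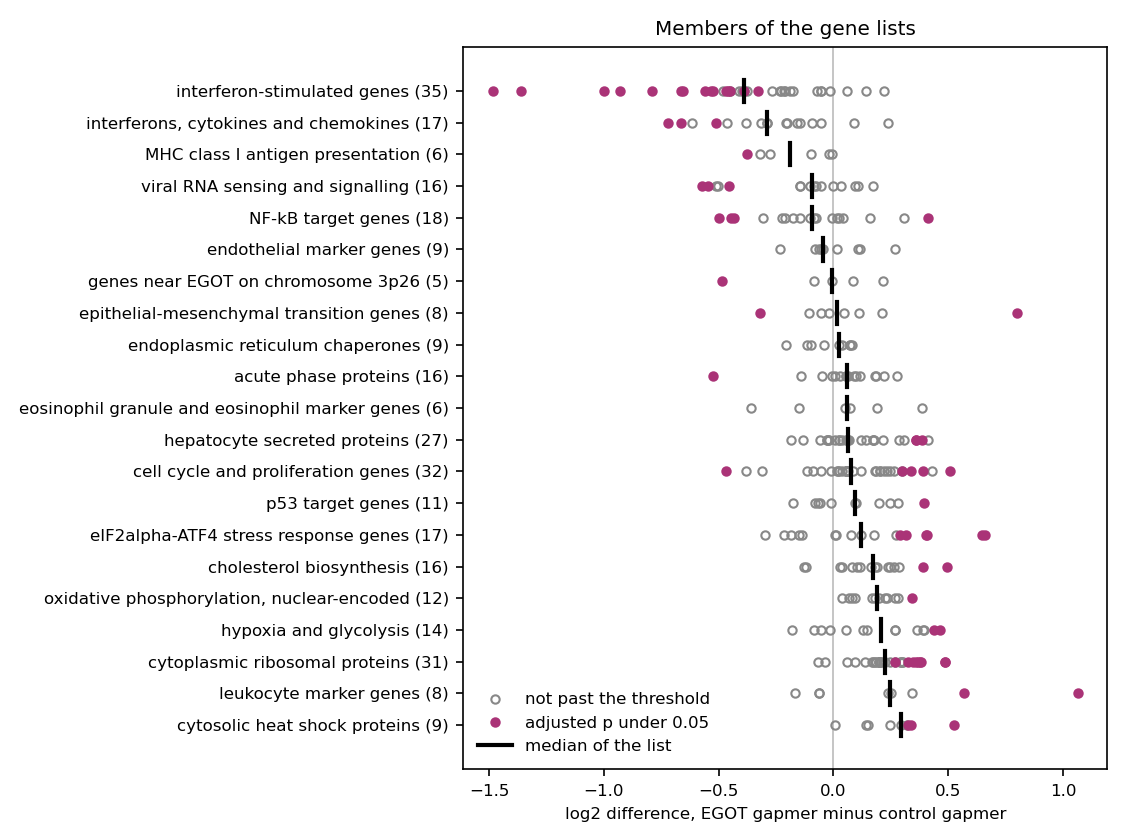
Log2 difference (EGOT gapmer minus control gapmer, 3 arrays each) of every measured member of the 21 tested gene lists, with the number of members in brackets. Filled points passed the limma threshold, open points did not, and black bars mark list medians, which run from -0.39 for interferon-stimulated genes to 0.29 for the heat shock list.

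Genes that fell spanned longer stretches of the genome than genes that rose, a relation examined after the data had been seen. Spans were taken from NCBI RefSeq on GRCh38.p14. The median genomic span was 130 kb for the 475 genes that fell, 12.1 kb for the 770 that rose and 20.7 kb for those that did not pass. Spans over 100 kb belonged to 281 of the genes that fell (59.2%), to 19 of those that rose (2.47%) and to 1954 of the rest (14.4%). GPC6 spans 1190 kb, EPHA5 351 kb and FRYL 283 kb, whereas CD68 spans 2.47 kb and MT1H 1.32 kb. Of the leading genes some go the other way, as TAAR3P, EGOT and IFI44L fell with spans of 1.08, 2.4 and 25.7 kb, and ACSL5 rose with a span of 54.3 kb. Among the brighter protein-coding genes the median log2 difference was 0.17 in the 1369 genes of shortest span (0.27 to 9.82 kb) and -0.13 in the 1368 of longest span (88.4 to 1550 kb). In the former 233 rose and 16 fell, and in the latter 15 rose and 264 fell. The ribosomal protein genes have a median span of 5.06 kb and those of oxidative phosphorylation 9.18 kb. The median is 17.7 kb for cholesterol biosynthesis, 13.7 kb for heat shock proteins and 16.3 kb for interferon-stimulated genes. With the trend on span removed from each array, 671 genes passed, 346 higher and 325 lower, of which 605 were among the 1245. The cholesterol and oxidative phosphorylation lists then no longer passed (camera adjusted p = 0.11 and 0.107), while the heat shock and ribosomal protein lists still passed.

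**Figure D3:**
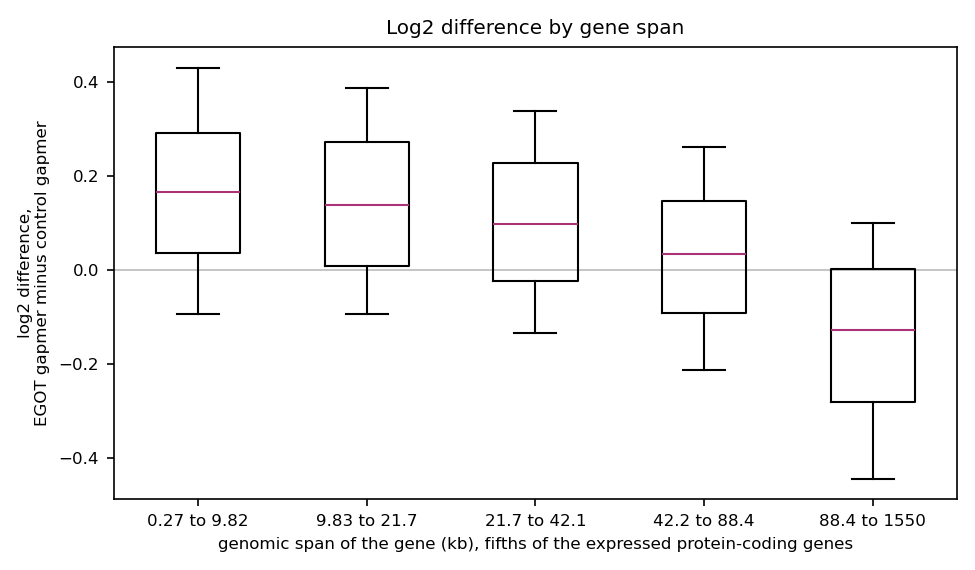
Log2 difference (EGOT gapmer minus control gapmer, 3 arrays each) of the brighter protein-coding genes, in 5 groups of increasing genomic span in kb. Boxes give the quartiles with the median as a line, and whiskers run from the 10th to the 90th percentile. The medians are 0.17, 0.14, 0.10, 0.03 and -0.13.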

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

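The test of PKR and poly I:C delivery was chosen after the result was seen, as was the removal of the gene span trend; the bounds of the other tests were set before their results were seen, though the span pattern itself came from the data. The probe sets with no gene name here, 28794 of them, were fitted on their own because they lie outside the gene comparison, and 1 passed the threshold, higher with the EGOT gapmer (limma, 3606 at an unadjusted p under 0.05). With a variance trend and robust estimation 959 passed, 583 higher and 376 lower. Their median level was 4.68 on the log2 scale, against 6.09 for the named ones.

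The 6 arrays can be divided into 3 and 3 in 10 ways. The real division gave 1245 genes and the highest of the others gave 0, so 1 of the 10 reached the real count, and 10 divisions are too few for a share under 0.05.

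Long genes were lower and short genes higher with the EGOT gapmer. A slope on span in single arrays, unrelated to the gapmer, is argued against. Among the brighter protein-coding genes, each log2 value was taken as a deviation from the gene's mean over all arrays and regressed on log10 span. These slopes were 0.0772, 0.115 and 0.104 in the control gapmer arrays and -0.101, -0.0951 and -0.1 in the EGOT gapmer arrays. The gap between the groups was 0.172, against ranges of 0.0379 and 0.00565 within the groups. Because of the centring, the slopes compare arrays with each other and do not give the relation of expression itself to span. Probe set brightness is argued against as the cause. Genes that fell had a median span 4.63 times that of genes of matched brightness (130 against 28.1 kb, permutation p = 0.0001, the smallest that 10000 draws can give). The draws resampled genes and not arrays, so this p leaves out the spread between arrays. They were not matched on gene type. Among protein-coding genes alone, without matching, the median span was 136 kb for those that fell and 26.9 kb for those that did not pass. Cleavage of some long transcripts at partial matches to the gapmer, which would pull down a tail, stays open. The values for this again cover only the brighter protein-coding genes. From the group of shortest span to that of longest span the median moved by -0.295 and the 10th percentile by -0.35, a ratio of 0.844. Its 95% bootstrap interval over genes, 0.771 to 0.935, lies above the bound of 0.5 set for a tail. The interval includes the bound of 0.8 set for a shift of the whole distribution. The 90th percentile, looked at afterwards, was 0.431 in the group of shortest span and 0.0996 in that of longest span, so the upper end differed too. The medians of these groups were 0.166 and -0.129. The contrast therefore mixes a rise of short genes with a fall of long ones, and it does not decide how many long transcripts were affected. Matches to the gapmer sequences in other transcripts were not searched here, so cleavage of most long transcripts was not tested. The loss of EGOT, another action of this 1 gapmer and a batch that followed the groups also stay open, because the design holds no second gapmer.

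Interferon-stimulated genes were lower with the EGOT gapmer. The span trend is argued against as the cause, since after its removal the list's median was -0.478, against -0.391 before. The camera adjusted p was then 1.92e-16. The bootstrap interval of -0.545 to -0.31 resampled the list's genes and not the arrays, so it leaves out the spread between arrays. Less PKR plasmid or poly I:C reaching these cells may be a cause and stays open: EIF2AK2 had a log2 difference of -0.572, as such a difference in delivery would give, but it is itself induced by interferon, and the ATF4 response genes, which less PKR activity would not raise, decide nothing, since 6 of 17 rose but 2 did once the span trend was removed (list median 0.0664, camera adjusted p = 0.276). The camera result needs the preset correlation between genes here, with an adjusted p of 0.278 when it was estimated. The loss of EGOT, the biological explanation the design names, stays among the open ones, untested against other actions of the gapmer.

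Ribosomal protein genes were higher with the EGOT gapmer. After removal of the span trend the median went from 0.226 to 0.131, with a camera adjusted p of 4.68e-06. The bootstrap interval, which resampled the list's genes and not the arrays, was 0.105 to 0.198. The trend was fitted over all genes, dim ones included, and may remove too little from brighter short genes. Before removal the brighter protein-coding genes of shortest span had a median of 0.166. A relation with span as the whole cause therefore stays open. Part of the shift went with the trend, and the 9 members that had passed singly became 0. The camera result again needs the preset correlation, with an adjusted p of 0.262 when it was estimated. Loss of EGOT and other actions of the gapmer were not told apart here either.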

How the results depend on the processing

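Removal of the gene span trend was chosen after the data were seen. Every alternative kept the direction of EGOT and of the 24 leading genes where they were tested (EGOT and 5 others were not among the brighter genes). EGOT stayed past the threshold except with the replicate block, with log2 differences of -1.84 to -1.76 and of -1.92 to -1.67 when 1 array was left out (highest limma adjusted p 0.0407). The 2 other treatments of several probe sets, median centring, array weights and both normalizations kept the count of genes within 1.5 times. The brighter genes gave 2547 genes (1688 higher, 859 lower) and a variance trend with robust estimation 2502 (1660 higher, 842 lower). Testing against a log2 difference of 0.26, a stricter test, left 11 (4 higher, 7 lower), so few genes were shown to differ by more than that. Span trend removal gave 671, with 346 higher, and ended the call of APOA4 (0.853 to 0.774, limma adjusted p 0.0578) and MT1H (0.899 to 0.832, limma adjusted p 0.0548), whose standard errors were 0.183 and 0.179 before and 0.178 and 0.186 after. Leaving out 1 array gave 9 to 579 genes, 2 to 389 higher and 7 to 258 lower, with fewer arrays to test. Of the 24 leading genes 18, 7 and 16 passed without control gapmer replicates 1, 2 and 3, and 23, 21 and 21 without EGOT gapmer replicates 1, 2 and 3. Of the 15 interferon-stimulated genes that fell, 1, 0 and 2 and then 7, 10 and 3 passed, all 15 below 0 each time. With the mean of its probe sets HIVEP2 had a log2 difference of -0.421 (-1.12 to -0.421 over its alternatives) and LYZ of 1.13 (0.474 to 1.13). Among genes named from the lists APOA1, PHGDH and MCM2 passed in 5 of 10 alternatives and ZEB2 in 1 of 9 (limma adjusted p 0.0494 to 0.115).

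With the replicate block 0 genes passed, 0 higher and 0 lower (limma, 3438 at an unadjusted p under 0.05), and EGOT had a difference of -1.76 with an adjusted p of 0.0543 (1.62e-05 to 0.0543 over its alternatives). No effect shared by arrays of the same number was seen: their deviations correlated by -0.054 to 0.0394, and 1 of 6 arrays correlated best with its own number. The labels do not say what a shared number means, so a pairing of the samples is not excluded.

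Of 9 lists, 0 passed with an estimated correlation. The adjusted p was 0.278 for interferon-stimulated genes, viral RNA sensing and oxidative phosphorylation, 0.112 for cytokines, 0.49 for NF-kB targets and cholesterol biosynthesis, 0.238 for heat shock proteins and 0.262 for MHC class I and ribosomal proteins. Fry tests a list against no change and not against the other genes, and the median log2 difference over all genes was itself 0.0372. By fry 14 lists passed, but not NF-kB targets (0.0699). Those also missed with every probe set (0.065), their range being 0.0198 to 0.0811 without 1 array and up to 0.49 over the other alternatives. Cholesterol biosynthesis missed among the brighter genes (0.0699) and with the span trend removed (0.11), with 0.0132 to 0.0844 without 1 array. Oxidative phosphorylation missed with the span trend removed (0.107), with 0.00331 to 0.278 over its alternatives. Some lists that had not passed did so elsewhere, such as the ATF4 response with the variance trend (0.0356) and by fry (0.017), leukocyte markers with every probe set (0.0288) and by fry (0.0305), cell cycle with the variance trend (0.0423) and by fry (0.0488), hepatocyte secreted proteins (0.0214) and p53 targets (0.0305) by fry, and hypoxia and glycolysis in 4 of 12 alternatives (0.0349 to 0.52).

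Reversals concerned differences that passed in neither setting. DCN was -0.0652 after quantile normalization, -0.0611 after cyclic loess, -0.0156 with the span trend removed and -0.00572 to 0.0900 without 1 array, turning without control gapmer replicate 2. With the span trend removed CNTN4 was 0.111 and MANF -0.00606. BST2 ranged from -0.153 to 0.0242 without 1 array, turning without control gapmer replicate 1 (0.00255) or EGOT gapmer replicate 2. Among lists, epithelial-mesenchymal transition turned with an adjusted p of 0.99 after cyclic loess, 0.953 after median centring, 0.954 with the variance trend, 0.9 with array weights, 0.91 with the replicate block, 0.771 and 0.446 with the mean of probe sets and every probe set, 0.849 with the span trend removed and 0.336 by fry. It also turned without control gapmer replicate 3 (0.83), EGOT gapmer replicate 1 (0.75) and EGOT gapmer replicate 2 (0.866), while all 6 fits without 1 array ranged from 0.734 to 0.955. Acute phase turned with every probe set (0.881), with the span trend removed (0.742) and without EGOT gapmer replicate 3 (range 0.367 to 0.828). With the span trend removed, genes near EGOT (0.992) and endothelial genes (0.901, and 0.998 by fry) turned, as did eosinophil genes by fry (0.988) and without control gapmer replicate 2 (0.728) or EGOT gapmer replicate 2 (0.93, range 0.382 to 0.93). Where construction does not give it, the cause was not tested. Signal over background is unknown here, so dim genes such as DCN are limited most.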

Other observations

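These groups were formed after the data were seen, from symbols that share a stem, and tested with camera at the preset correlation. Of 232 stems with at least 8 measured genes 18 passed, 12 higher and 6 lower with the EGOT gapmer, and 0 passed with an estimated correlation (adjusted p = 0.893). Metallothioneins, small metal-binding proteins, were higher, with a median log2 difference of 0.28 over 11 genes (camera adjusted p = 0.0336). MT1G rose by 0.83, MT1H by 0.90 and MT1M by 0.57, whereas MT4 had a difference of -0.30 that did not pass (limma adjusted p = 0.103). Glutathione peroxidases were higher, with a median of 0.31 over 8 genes (camera adjusted p = 0.0427). GPX2 rose by 0.91, GPX1 by 0.54 and GPX4, which reduces lipid peroxides, by 0.43. Of 9 snoRNA host genes of the SNHG series, SNHG5 rose by 0.48 and SNHG15 by 0.42, and the median was 0.24 (camera adjusted p = 0.0336).

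Stems of mitochondrial ribosomal proteins and of the outer membrane translocase were higher as well. Symbols beginning with MRPL, for the large subunit of the mitochondrial ribosome, had a median of 0.20 over 52 genes, of which 12 rose and 0 fell (camera adjusted p = 1.32e-06). Those beginning with MRPS, for the small subunit, had a median of 0.21 over 25 genes, of which 6 rose and 1 fell (camera adjusted p = 0.0151). Those beginning with TOMM, for import through the outer membrane, had a median of 0.28 over 10 genes, of which 3 rose (camera adjusted p = 0.00243), whereas TIMM, for the inner membrane, did not pass, with a median of 0.23 over 13 genes (camera adjusted p = 0.229). Chemokines of the CXCL series had a median of -0.14 over 13 genes, of which 2 fell (camera adjusted p = 0.0248). The other stems that were lower were SMAD, GALNT, HERC, EXOC and DENND. The median of 0 of the 18 stems changed sign under quantile normalization, cyclic loess, median centring or removal of the span trend, and 15, 15, 16 and 4 of them passed in that order. The 4 were MRPL, RPS, TOMM and CXCL, so that metallothioneins (0.0617), SNHG (0.125) and glutathione peroxidases (0.117) no longer passed once the span trend was removed. Their medians then were 0.21, 0.15 and 0.22.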
